A study of Mus musculus with 2 samples.

How the data were processed

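The series holds 2 Affymetrix Mouse Gene 1.0 ST arrays of total RNA from bone marrow-derived dendritic cells, 1 array for CBA/J and 1 for C57BL/6. Per the labels' protocols, marrow cells were grown for a week in medium with a supernatant that contains GM-CSF and received no treatment. Per the series' design text, cells from individual mice were plated in replicate wells that were pooled before RNA extraction, and the number of mice is not given in the sources used here. Pooled wells are not replicates, so each strain counts as 1 sample.

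The deposited table gives a log2 expression value per probe set and array, and the authors had already processed these values. Affymetrix Expression Console 1.1 is named in the submitters' processing notes. The background correction, summarization and normalization are not given in the sources used here. A deposited column of ratios, CBA over BL/6, equals 2 to the power of the difference of the log2 columns, per the file headers and to rounding. The series matrix holds log2 values identical to the deposited table for every probe set. Across all 35557 probe sets the array medians were 6.00 in CBA and 6.01 in BL/6, and the 75th percentiles were 7.60 and 7.51.

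Probe sets were named from the deposited annotation. In all, 24422 probe sets named 1 gene, 112 named several and stayed unnamed, and 11023 named none, control probe sets included. Symbols were updated through the RefSeq gene table of assembly GRCm38, 18877 by accession, 2316 because the symbol was current and 1581 by synonym, and 1648 kept the name in the file. In 25 cases a spreadsheet had turned a symbol into a date, and all 25 were recovered through the accession. GRCm38 served for names and gene order only. A gene with several probe sets, of which there were 1267, took their mean.

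Groups came from the strain labels. The filters, thresholds, 40 gene lists and the rule for named genes were set before the data were examined. A gene counted as expressed when the higher array reached the median of all non-control probe sets, a log2 value of 6.05. Genes are described by size alone, with a threshold of 2-fold. With 1 array per strain no p-value was computed for a strain difference, since genes are not replicates. The Wilson interval and the random draws of genes used below treat genes as independent and describe these arrays only. The share of differing genes higher in CBA has a 95% Wilson interval. For each list the median difference of the expressed members was set beside 10000 random lists of the same size matched on mean expression in 20 bins, and lists with under 3 expressed members were not placed. The central 95% of the random medians describes these arrays and is no test of the strains.

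The text names the 15 genes with the largest difference in each direction among expressed and uniquely named genes, without predicted or clone names, olfactory and vomeronasal receptors, small RNAs and antigen receptor segments. It also names up to 4 expressed members of each list with the largest absolute difference, and 26 genes chosen in advance whatever their value. Some genes that this rule selects are not reported here. Genes named outside this rule in the accounts of gene order and in the closing section were chosen after their values were seen.

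The level called background is the 75th percentile of the 5222 negative control probe sets of an array, 6.57 in CBA and 6.37 in BL/6, a choice made after seeing the data. A gene below it on 1 array has only a bound there, and "at least N-fold" compares the brighter value with that level. No fold is given where the brighter value is itself below its array's level or below the level of the dimmer array. Bright negative controls read well above it, so it is a working limit and not a detection call.

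Gene order was tested by counting differing genes with another differing gene among the 2 neighbours on each side in the order of expressed genes, beside 1000 random draws. For this count, genes whose symbols share the first 3 letters were taken as 1 family, which only stands in for shared sequence. Alternatives were no filter, filters at the 75th percentile and at a log2 value of 6, and thresholds of 1.5-fold and 3-fold. Others were median centring, quantile normalization, loess centring (span 0.3), the brightest probe set or every probe set, and the series matrix. A further one left out H2, Klr, antigen receptor, olfactory and vomeronasal receptor genes. A filter on the negative controls, raising values below background to that level, and counting probe sets with identical values once were added after seeing the data.

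The calculations were tested on simulated data for the comparison of CBA with BL/6 over 12008 genes, with noise of the observed spread. Of 100 genes planted at a log2 difference of 1.5 in either direction, 98 were recovered at 2-fold, as were 100 of 100 planted at 3. Of the genes left alone, 2 reached 2-fold. The simulated noise was normal, with the spread of the bulk of the genes, so this count checks the calculation and is no rate of false calls. Control probe sets on the real arrays were 2-fold apart far more often, as given below. Of 100 simulated lists of 12 genes shifted by 0.5, 100% lay outside the central 95% of random lists, and of 100 lists left alone 1.0% did. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.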

Results

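Gene expression was compared between unstimulated dendritic cells grown from the bone marrow of CBA/J (CBA) and C57BL/6 (BL/6) mice. These are 2 inbred laboratory strains, and the cells were grown with GM-CSF, a cytokine that drives marrow cells towards dendritic cells and macrophages. RNA of each strain was hybridised to 1 Affymetrix Mouse Gene 1.0 ST array, which reads each gene through a set of short probes. Both arrays carried 35557 probe sets, which named 21885 genes, and 12008 of these counted as expressed. There were no replicates, so no difference below has a replicate check or a p-value. Strain cannot be told apart from mouse, culture or array, and the number of arrays limits the precision of every value. Differences are CBA minus BL/6 on the log2 scale.

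Both arrays gave similar profiles. Across the expressed genes Pearson's r was 0.96, which describes genes on these arrays and not independent replicates. The difference was under 1.5-fold for 93.3% of expressed genes, and its median was 0.07. The housekeeping genes Actb and Gapdh differed by 0.02 and -0.06. Xist, the RNA of the inactive X chromosome, read 10.78 in CBA and 10.62 in BL/6, while the Y-linked Ddx3y was not well above background on either array. Itgax, which encodes the dendritic cell integrin CD11c, read 10.50 in CBA and 10.63 in BL/6.

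The comparison asks which genes differ between dendritic cells of both strains before any stimulus. The CBA array was higher for the MHC class II chain H2-Ea, the histidine-degrading enzyme Hal, the interferon-inducible Ifi202b and the chitinase-like Chil1. It was also higher for the endosomal protease Ctse, the C-type lectin Cd209a and the scavenger receptor Colec12. The BL/6 array was higher for the chemokines Ccl5, Ccl22 and Ccl17, the co-stimulatory genes Tnfrsf9 and Tnfsf4, the SLAM receptor Slamf7 and the MHC class I heavy chain H2-D1. In all, 153 expressed genes were at least 2-fold higher in CBA and 90 were at least 2-fold higher in BL/6, so 63.0% of the 243 differing genes were higher in CBA (95% Wilson interval 56.7 to 68.8%, counting error only). With the differences centred on their median the counts were 137 and 109. With values below background raised to that level, so that each gene stands at its bound, they were 112 and 55. The cut for expressed genes lies below the level called background on both arrays. With the negative control filter 10352 genes were kept, and the counts were 142 and 86.

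H2-Ea serves as a check of the labels, since mice of the BL/6 haplotype do not transcribe it. It read 11.18 in CBA and 4.72 in BL/6, where it was not well above background, and was at least 28.1-fold higher in CBA. Hal was at least 23.9-fold higher, Chil1 at least 13.4-fold, Ctse at least 12.5-fold, the eosinophil-type ribonuclease Rnase2a at least 11.8-fold, Colec12 at least 10.3-fold and Cd209a at least 9.22-fold. The bounds were smaller for Cd209c at 3.69-fold, the adhesion molecule Nectin3 at 3.39-fold, Ifi202b at 3.16-fold and Retnla, a resistin-like secreted protein, at 2.63-fold. They were 2.23-fold for Ly6g, 2.05-fold for the transporter Abca9 and 1.80-fold for the zinc finger gene Zfp791. Zfp979 was also among the 15 genes with the largest differences, but was not well above background on either array.

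Among the 15 genes with the largest differences towards BL/6, Ccl5 had a difference of -2.83, Tnfrsf9 of -2.65 and H2-D1 of -2.62. Chil3, a chitinase-like secreted protein, had -2.48, Slamf7 -2.20, Ccl22 -1.81 and Ccl17 -1.74. For genes not well above background in CBA only a bound can be given. H2-Q6 was at least 6.78-fold higher in BL/6, Tnfsf4 at least 2.52-fold, the scaffold gene Mpp7 at least 2.27-fold and the mast cell protease Cpa3 at least 2.05-fold. The bounds for Trim12a, the reductase Akr1e1 and Trim30d were 1.44-fold, 1.41-fold and 1.04-fold. H2, Cd209, Ly6, Ear and Klr genes have close relatives whose RNA can bind the same probes, so their single values are uncertain.

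**Figure D1:**
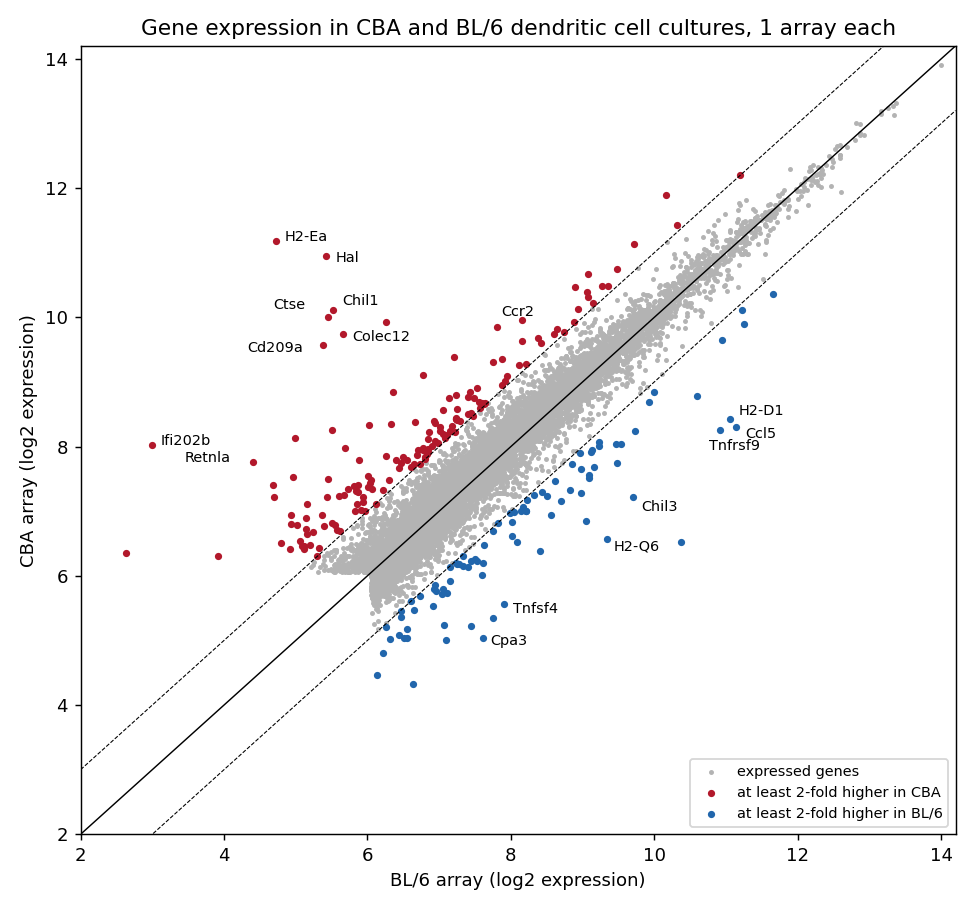
Expression of the 12008 expressed genes on the BL/6 array (horizontal axis, log2) and the CBA array (vertical axis, log2). Each point is 1 gene, the solid line marks equality, the dashed lines mark 2-fold, and the coloured points are the 153 genes at least 2-fold higher in CBA and the 90 at least 2-fold higher in BL/6.

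Of the 40 gene lists, 34 had at least 3 expressed members. The median difference of 16 lay outside the central 95% of random lists of equal size and brightness, where 1.70 would be expected if lists were drawn at random. The lists share members, and this range describes these arrays only. The median difference over all expressed genes was 0.07, so most of them read higher in CBA. Counts of members higher in CBA are to be read against that shift, which the random lists carry too.

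C-type lectin receptors, which bind sugars on microbes, had a median of 0.27 over 20 expressed members, against -0.06 to 0.19 for matched random lists, and 0.18 without a brightness filter. Of these, 7 read at least 2-fold higher in CBA, among them Cd209a, Cd209c and Cd209d, the last with a bound of only 1.33-fold. The oxidised lipoprotein receptor Olr1 was the 1 member that read at least 2-fold higher in BL/6, with -1.56. The 7 also include the Clec4a genes of a run on chromosome 6 described below. Relatives within the Cd209 and Clec4a families may share probes, and no alternative left these families out. What the list median would be without them was not computed. The fungal receptors Clec7a, Clec4n and Clec4e, all bright on both arrays, differed by -0.10, 0.09 and 0.18. Toll-like receptors and co-receptors had a median of 0.52, against -0.06 to 0.25 for random lists, and 9 of 11 were higher in CBA. Without a filter the median of all 15 measured was 0.31. Tlr8 had a difference of 1.62, Tlr9, a sensor of DNA, of 0.64 and Ly86 of 0.64, while Tlr2 had 0.29 and Tlr4 0.11. Scavenger and phagocytic receptors had a median of 0.41, against -0.06 to 0.23 for random lists, with 11 of 12 higher in CBA. Beside Colec12, Stab1 had a difference of 0.94 and Mertk of 0.80, and Marco, not well above background in BL/6, was at least 1.54-fold higher in CBA.

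Inflammasome genes had a median of 0.28, against -0.06 to 0.26 for random lists, and none of the 13 was 2-fold apart. Nlrc4 had the largest difference, 0.74. The median lay inside the range in 5 of 11 alternatives, at 0.16 with quantile normalization, 0.15 with loess centring, 0.25 with the 75th percentile filter, 0.26 with the negative control filter and 0.25 with genes at their bound. Median centring and the series matrix are among the 11 but could not change its place among the random lists. Cholesterol and oxysterol response genes had a median of 0.48, against -0.05 to 0.22 for random lists. Of these, 14 of 16 were higher in CBA, none by 2-fold. The sterol synthesis genes Cyp51 and Hmgcs1 had differences of 0.95 and 0.92, and the regulator Insig1 of 0.82. The oxysterol response genes in the list lay between -0.04 and 0.32, so the median speaks for the sterol synthesis and uptake genes and not for an oxysterol response. Chemokine receptors had a median of 0.32 over 8 members that went both ways, but with genes at their bound it was 0.073 and inside the range. The median was 0.15 without a filter and 0.50 with every probe set. Ccr2, which guides monocytes, had a difference of 2.05, while Ccr7, which guides mature dendritic cells to lymph nodes, had -1.35 and Cxcr4 -0.60. Ccr6 was not well above background on either array.

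MHC class I presentation genes were lower in CBA for 18 of 20 expressed members, with a median of -0.33 against -0.05 to 0.19 for random lists. Of these 20, 16 lie on chromosome 17, polymorphic H2 genes among them, with a median of -0.37. The 4 elsewhere had a median of -0.18, with 3 lower in CBA, a split made after the values were seen. The list median thus speaks mainly for genes on chromosome 17, and weaker binding of CBA RNA to their probes was not tested. H2-Q6 was at least 6.78-fold higher in BL/6, and H2-D1 had a difference of -2.62, H2-K1 of -0.92 and the peptide transporter Tap1 of -0.69. MHC class II presentation genes had a median of -0.17, against -0.07 to 0.20, and 8 of 12 were lower in CBA. Beside H2-Ea, H2-Ab1 had -1.28, the class II transactivator Ciita 0.92, H2-Oa -0.72, H2-Eb1 -0.57 and H2-Aa -0.26. With genes kept only above the 75th percentile of brightness, the class II median was -0.07 and inside the range, and without a filter it was -0.26.

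Alternative activation genes had a median of -0.18, outside the range of -0.06 to 0.23 (-0.28 with loess centring), with 3 members that read at least 2-fold higher in each strain. Retnla was at least 2.63-fold higher in CBA, while Chil3 had a difference of -2.48, Ccl22 of -1.81 and Ccl17 of -1.74. NF-kB feedback and immediate early genes had a median of -0.04, against -0.01 to 0.21, and none of the 23 was 2-fold apart. The median was -0.10 with median centring, -0.12 with quantile normalization and -0.14 with loess centring. Traf1 had -0.69, Birc3 0.50, Rel -0.50 and Fosb 0.49.

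**Figure D2:**
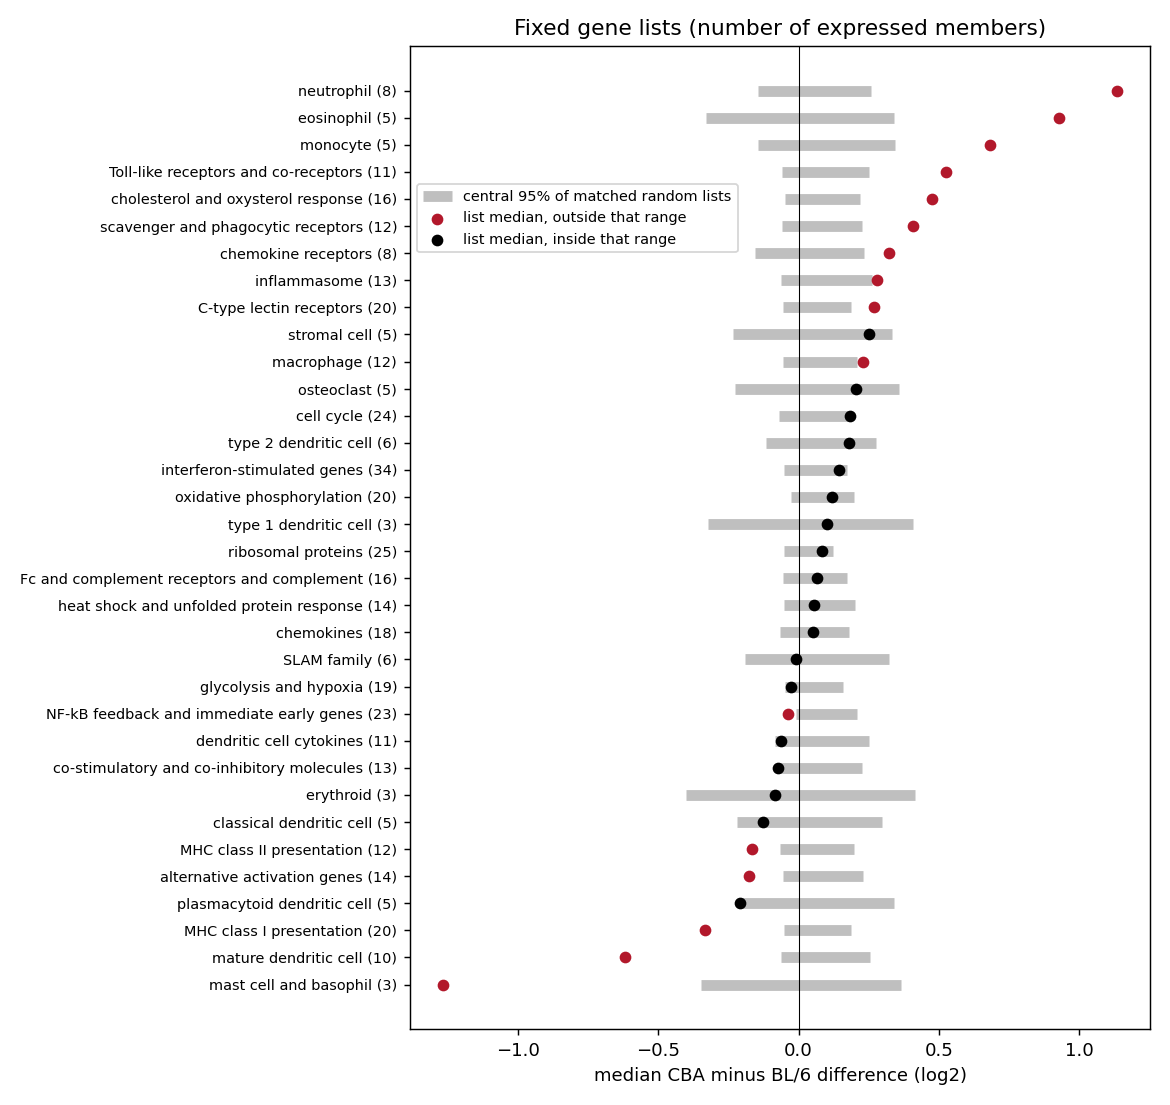
Median CBA minus BL/6 difference (log2, horizontal axis) of the 34 lists with at least 3 expressed members, whose number is in parentheses. Grey bars are the central 95% of 10000 random lists of equal size and brightness, and the 16 red points lie outside them, from -1.27 for mast cell and basophil genes to 1.13 for neutrophil genes.

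Markers of other cell types differed beside these groups. Neutrophil markers had a median of 1.13, and all 8 expressed members were higher in CBA, 4 of them at least 2-fold. Without a filter the median of all 12 measured was 0.68. Ly6g was at least 2.23-fold higher, and the granule gene Ngp had a difference of 2.18, S100a9 of 1.40 and S100a8 of 1.27. In BL/6, S100a9 read 6.40 and S100a8 6.47, just above the background level of 6.37 there, so both differences are close to bounds. Monocyte markers had a median of 0.68, with Ccr2 at 2.05, the proteoglycan Vcan at 1.60 and Ly6c1, which went the other way, at -1.63. The monocyte median was 0.42 without a filter or with every probe set. Macrophage markers had a median of 0.23, against -0.06 to 0.21 for random lists, and none of the 12 was 2-fold apart. The Fc receptor Fcgr1 had a difference of 0.99, Adgre1, which encodes F4/80, of 0.99 and Mertk of 0.80.

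Mature dendritic cell markers were higher in BL/6. Their median was -0.62, against -0.06 to 0.25 for random lists, and 9 of 10 were lower in CBA, 4 of them at least 2-fold. The median was -1.07 with the 75th percentile filter and -0.43 without a filter or with the filter at a log2 value of 6. Ccl22 had a difference of -1.81, Ccl17 of -1.74, Ccr7 of -1.35 and Cd83 of -1.33. Eosinophil markers had a median of 0.93 over 5 members, but this is the value of Ear1, which was not well above background on either array, and with genes at their bound the median was 0 and inside the range. Siglecf had a difference of 1.102, Ear2 was at least 1.82-fold higher in CBA, and for Ear6, not well above background in CBA, no fold can be given. Mast cell and basophil markers had a median of -1.27 over 3 members, the value of the histamine-forming enzyme Hdc, which like Cpa3 was not well above background in CBA. With genes at their bound the median was -0.83. Cpa3 and Hdc were at least 2.05-fold and 1.78-fold higher in BL/6, and Gata2 had a difference of 0.58. Without a brightness filter the eosinophil and mast cell medians were 0.16 and -0.10, both inside the range, as were the eosinophil median of 0.21 with the negative control filter and the mast cell value of 0.58 with the 75th percentile filter, where 1 gene was left.

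**Figure D3:**
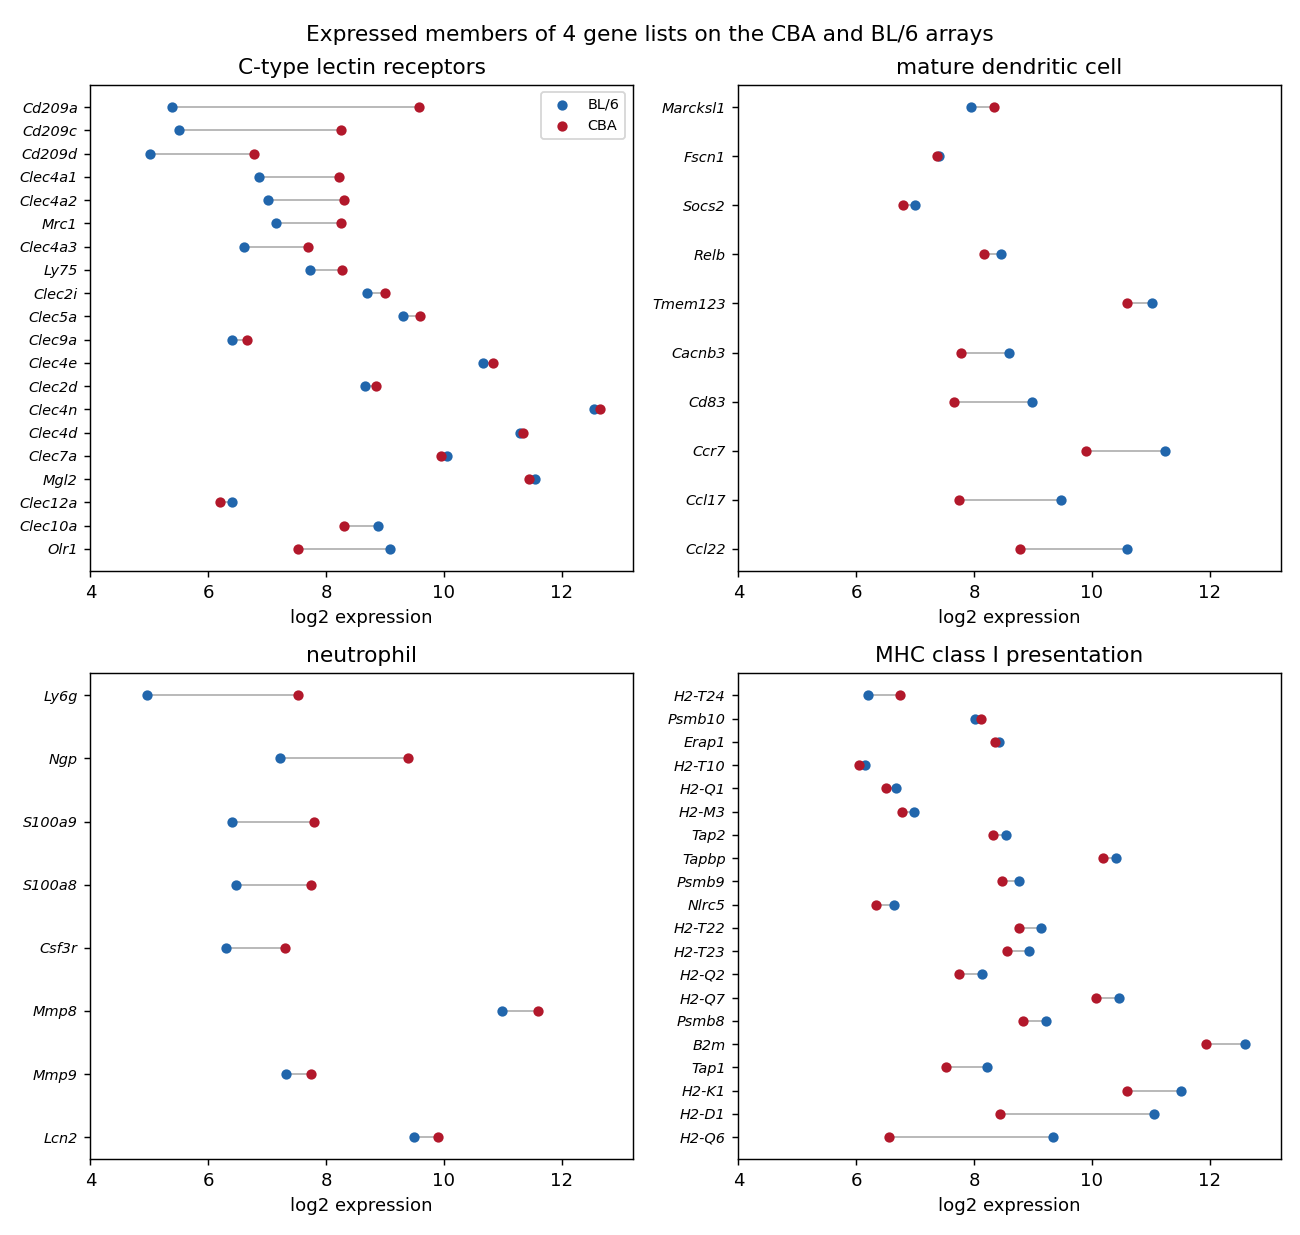
Expression (log2, horizontal axis) of the expressed members of 4 gene lists on the CBA array (red) and the BL/6 array (blue), 1 point per gene and array. All 8 neutrophil markers lie higher in CBA, and 9 of the 10 mature dendritic cell markers and 18 of the 20 MHC class I presentation genes lie higher in BL/6.

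The other 18 lists with at least 3 expressed members lay inside the range of random lists, 7 of them not in every alternative. Their medians were small, and 17 of them moved by over 1.5 times or changed sign in some alternative. The sign changed for chemokines and heat shock genes with median centring, at -0.014 and -0.0097, for osteoclast markers without a filter, at -0.11, for classical dendritic cell markers with the 75th percentile filter, at 0.37, and for erythroid markers with loess centring, at 0.0205. Dendritic cell cytokines had a median of -0.06 and none of the 11 was 2-fold apart. Osm had a difference of -0.68, Il15 of 0.51, Il1a of -0.28, Tnf of -0.19 and Il1b of -0.17, while Il6, Il10, Il12a, Il12b and Il23a were not well above background on either array. Chemokines had a median of 0.05, with Cxcl14 at 1.33 beside the 3 named above. Co-stimulatory and co-inhibitory molecules had a median of -0.07, close to the lower edge of -0.08, with Cd83 at -1.33, Cd80 at -0.92, Cd86 at 0.08 and Cd40 at 0.03, beside Tnfsf4, at least 2.52-fold higher in BL/6. Interferon-stimulated genes had a median of 0.15, and Ifi44, the only one of 34 that read at least 2-fold apart, had a bound of 1.92-fold towards CBA. SLAM family genes had a median of -0.01, with Slamf7 at -2.20. Fc and complement receptors and complement had 0.07, with the anaphylatoxin receptor C3ar1 at 1.42 and Fcgr4 at least 1.68-fold higher in CBA.

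Among the lists of general cell functions, cell cycle genes had a median of 0.19, at the upper edge of 0.19, with 19 of 24 higher in CBA and Mki67, a proliferation marker, at 0.89. Oxidative phosphorylation genes had 0.12, ribosomal protein genes 0.08, heat shock and unfolded protein response genes 0.06 with Hspa1a at 1.13, and glycolysis and hypoxia genes -0.03. For Nnt, a mitochondrial transhydrogenase, the mean difference was 0.24, but its probe sets pointed opposite ways, with 0.77 and -0.28.

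Classical dendritic cell markers had a median of -0.13 with Dpp4 at 1.05, type 1 dendritic cell markers 0.10 and type 2 dendritic cell markers 0.18, with Cd209a among them. Plasmacytoid dendritic cell markers had -0.21, at the lower edge of -0.21, with Bst2 at -0.75. Stromal cell markers had 0.25, osteoclast markers 0.20 with Dcstamp at -0.90, and erythroid markers -0.08. The remaining lists had under 3 expressed members. Among killer lectin-like receptors these were Klrb1f, at least 1.905-fold higher in CBA, and Klrb1b, at least 1.26-fold higher in BL/6. Among T cell markers they were Thy1 with -0.97 and Cd3e, which was not well above background on either array, and among myeloid progenitor markers Cd34 with 0.84 and Cebpe with 0.08. Prf1, not well above background on either array, was the only natural killer cell marker that counted as expressed, and Xist, with 0.16, the only expressed sex-linked gene, while none of the 9 B cell markers was expressed.

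Differing genes lay close together on the chromosomes. Of 235 differing genes with a known place in the gene order, 65 (27.7%) had another one among their 2 nearest expressed neighbours on either side. In 1000 random draws of as many expressed genes the median was 7.66% and the highest value 17.02%. On chromosome 8, Cd209a, Cd209d and Cd209c formed such a run, as did Ccl22 and Ccl17. Other runs were C3ar1 with Clec4a1, Clec4a3 and Clec4a2 on chromosome 6, S100a8 and S100a9 on chromosome 3, and Nectin3 and Retnla on chromosome 16. Of 27 runs, 20 held genes that differed in the same direction. No random level was computed for this count. Most differing genes were higher in CBA and several runs hold relatives that may share probes, so part of the agreement would arise anyway. When neighbours whose symbols share the first 3 letters were not counted the share was 14.5%, between the 95th percentile of the draws (11.5%) and their highest value (17.9%).

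Probe sets of the same gene give the repeat measurement within an array. In 753 genes with several expressed probe sets, the SD of the differences within a gene was 0.16. Of 219 pairs of probe sets with a member at least 2-fold apart, 210 (95.9%) pointed the same way, but most came from repeated probe sets with identical values. Counting identical values once, 45 of 53 pairs (84.9%) from 25 genes did, a count chosen after the values were seen. This covers probe error and not the spread between mice or cultures. Of 1182 expressed positive control probe sets, 18 (1.52%) were at least 2-fold apart, against 2.02% of expressed genes. Of 5222 negative control probe sets 10.5% were at least 2-fold apart, 394 higher in CBA and 156 higher in BL/6.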

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

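The tests of a higher background and of the neutrophil transcripts, the level that counts as background and the values at their bound were chosen only after the results were seen, while the tests of the direction of the differences and of the gene order were planned. The test of a higher background is the last of 3 forms tried. Neither a sample far from its group nor a difference between groups under a shared contrast can arise with 1 array per strain.

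Probe sets without a gene name enter no comparison of the report. Of 4589 such probe sets, those that were at least 2-fold apart and above the background of the brighter array had 16 distinct pairs of values, 12 higher in CBA and 4 higher in BL/6. At their bound, 6 and 2 of these were at least 2-fold apart. One matches an endogenous mouse mammary tumor virus, was not well above background in BL/6 and was at least 1.41-fold higher in CBA. The probe set of the microRNA precursor mir-155, an immune regulator, was not well above background in CBA and was at least 1.72-fold higher in BL/6. A repeated retroviral integrase cDNA, read by 27 probe sets with identical values, had a difference of -1.21.

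More genes were higher in CBA than in BL/6. Weaker binding of CBA RNA to probes designed on the BL/6 sequence would tilt the balance towards BL/6, but 63.0% of the differing genes were higher in CBA, with a Wilson interval that starts at 56.7%. The interval treats genes as independent, though differing genes lay beside each other. The share was 55.7% with median centring and 55.4% with quantile normalization, for which no interval was computed. Negative controls also lay towards CBA (394 against 156 at least 2-fold apart). A smaller loss of CBA signal could thus be hidden by the scaling and background of the arrays. A mismatch in single genes among the 90 higher in BL/6, such as the polymorphic H2 genes, stays open. Strain, the difference the design names, was not tested against mouse, culture or array.

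Differing genes lay beside each other more often than in random draws. Members of a family that share sequence could bind the same probes. Family was read from the first 3 letters of the symbol, which only stands in for shared sequence. Without neighbours of the same family the share was 14.5%, down from 27.7%. That value lies above the 95th percentile of the draws (11.5%) and below the highest draw (17.9%), so shared sequence cannot be told apart from other reasons for neighbouring differences. Stretches of sequence that differ between the strains were not tested.

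Neutrophil markers were higher in CBA and mature dendritic cell markers in BL/6, where 8 of 12 and 10 of 11 markers were expressed, and 0 and 5 of the expressed ones stand in another list too. A higher background on the CBA array, where negative controls had a median difference of 0.18, could raise the neutrophil median. With values below background raised to that level the median was 1.04. The central 95% of random lists treated alike ended at 0.24, with an SD of 0.084. Raising such values thus did not bring the median into that range. The list was singled out against such random lists and the value was seen beforehand, so this is no independent test and the background stays open as a cause. A larger share of neutrophils in the CBA culture may be involved, but 0 of the neutrophil transcripts Camp, Ltf, Retnlg and Cxcr2 were above background and higher in CBA, and none was above background in BL/6, so this cannot be told apart from a difference within the cultured cells. Weaker binding of CBA RNA to the probes of mature dendritic cell markers stays open, as does the strains' own make-up, which was not tested.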

How the results depend on the processing

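No replicate could be left out and no other split of the samples was possible with 1 array per strain, and no paired analysis was possible because each strain has 1 array. The negative control filter, the count of distinct probe set values and the values with genes at their bound were chosen only after the data were seen. For list medians, a move counted when it exceeded 1 SD of the matched random medians, and 62 of 373 values did, the mast cell and basophil median that turned among them. Where no cause is named below, the cause was not tested. Thresholds of 1.5-fold and 3-fold gave 514 and 40 genes higher in CBA and 292 and 21 higher in BL/6, and the 75th percentile filter, with fewer genes, left 52 higher in BL/6. With genes at their bound 55 were higher in BL/6, as fewer dim genes reached 2-fold. The share higher in CBA was 55.7% with median centring and 55.4% with quantile normalization, above 50% in every alternative, but no interval was computed for the alternatives. Of the 55 named genes at least 2-fold apart, 4 (Fcgr4, Dpp4, Hspa1a and Siglecf) were under 2-fold in some scaling, and 14 were so or had no fold at their bound. Of the 16 lists outside the range, 11 stayed outside in all 11 alternatives, and inflammasome, chemokine receptor, MHC class II, eosinophil, and mast cell and basophil lists did not. Among these alternatives, the series matrix holds identical values and median centring shifts a list and its random lists alike. Neither could change a list's place. Of the lists inside, 7 lay outside in some alternative, cell cycle among them. The mast cell and basophil median turned to 0.58 with the 75th percentile filter, where 1 gene was left, and was -0.10 with no filter. With no filter, medians were 0.18 for C-type lectins, -0.26 for MHC class II, 0.31 for Toll-like receptors, 0.15 for chemokine receptors, 0.011 for classical dendritic cells, 0.16 for eosinophils, -0.43 for mature dendritic cells, 0.42 for monocytes, 0.68 for neutrophils, -0.11 for osteoclasts and 0.049 for stromal cells. With the 75th percentile filter they were -0.070 for MHC class II, 0.41 for Toll-like receptors, 0.48 for cell cycle, 0.37 for classical dendritic cells, -0.18 for co-stimulatory molecules, 0.074 for interferon-stimulated genes, -1.07 for mature dendritic cells, 0.94 for neutrophils and 0.36 for osteoclasts. The log2 of 6 filter gave -0.43 for mature dendritic cells and 1.00 for neutrophils, and the negative control filter 0.21 for eosinophils. Genes at their bound gave 0.073 for chemokine receptors, 0.0101 for interferon-stimulated genes, -0.83 for mast cells and basophils and 0 for eosinophils. With every probe set, chemokine receptors had 0.50 and monocytes 0.42. Loess centring gave -0.43 for MHC class I, -0.14 for NF-kB genes, 0.39 for Toll-like receptors, -0.28 for alternative activation, 0.35 for cholesterol, -0.15 for cytokines, -0.015 for heat shock, 0.15 for inflammasome, 0.027 for interferon-stimulated genes, 0.16 for macrophages, -0.70 for mature dendritic cells, 0.046 for oxidative phosphorylation and 0.32 for scavenger receptors. Median centring gave 0.20 for C-type lectins, 0.0006 for Fc and complement genes, -0.40 for MHC class I, -0.10 for NF-kB genes, -0.014 for chemokines, -0.0925 for glycolysis, -0.0097 for heat shock, 0.080 for interferon-stimulated genes, 0.054 for oxidative phosphorylation and 0.0175 for ribosomal proteins. Quantile normalization gave -0.41 for MHC class I, -0.12 for NF-kB genes, 0.42 for Toll-like receptors, -0.25 for alternative activation, 0.38 for cholesterol, 0.16 for inflammasome, 0.052 for interferon-stimulated genes and 0.0415 for oxidative phosphorylation. Pairs of probe sets pointed the same way in 84.9% of cases with distinct values. Differing genes with a differing neighbour made up 19.6% with 1 neighbour, 42.6% with 5, and 14.5% without families. Signal over background limits genes such as Il6 and Il12b, whose differences were not measurable.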

Other observations

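The genes in this part were chosen after their values were seen. Of 20 Ms4a genes measured, which encode membrane proteins with 4 transmembrane parts, 6 were expressed, and 4 of these read at least 2-fold higher in CBA. Ms4a4a had a difference of 1.19 and was bright on both arrays, while Ms4a7 and Ms4a6c were at least 1.35-fold and 1.44-fold higher in CBA, and Ms4a6d had 0.38. Ms4a14 was not well above background on either array and Ms4a15 not in CBA, and no fold can be given for them. Both subunits of the interleukin-18 receptor were higher in CBA, Il18rap with 1.15 and Il18r1 at least 1.57-fold. Tmem176a and Tmem176b, neighbours on chromosome 6, both had 1.14. Gatm, an enzyme of creatine synthesis, had 2.32. The glyoxalase Glo1 had 1.12.

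Ly6g was at least 2.23-fold higher in CBA, but its relatives went the other way, Ly6c1 with a difference of -1.63, Ly6i at least 2.86-fold and Ly6a at least 1.31-fold higher in BL/6. Of the ribonuclease family, Rnase2a and Ear2 were at least 11.8-fold and 1.82-fold higher in CBA, Ear10 had a difference of 1.51, and no fold can be given for Ear1 and Ear6. Trim12a and Trim30d were at least 1.44-fold and 1.04-fold higher in BL/6, and their relatives Trim12c and Trim30a had -0.02 and 0.17. For the interleukin-10 receptor, Il10ra had 1.06 and Il10rb -0.82. Spp1, which encodes osteopontin, had -1.11. MHC class I presentation genes on chromosome 17 were lower in CBA for 15 of 16 expressed members, with a median of -0.37, and the 4 elsewhere had a median of -0.18, with 3 lower in CBA.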
